A study of Mus musculus with 4 samples.

How the data were processed

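Messenger RNA levels were measured by RNA sequencing in 4 libraries of mouse mammary cells, sorted as given below. There were 2 libraries from WT and 2 from ΔNp63 cKO animals. Each genotype had 1 library at 10 days and 1 at 5 weeks after tamoxifen (1.5 mg/ml, per the labels' protocols). Groups were taken from the genotype label and time points from the time label. Nothing in the labels says that the libraries came from separate animals. The p-values of single genes therefore measure only the spread between these libraries, which also includes any difference in how genotype acts at the 2 time points. List p-values with a preset correlation instead compare a list's genes with all other genes, and take genes of a list as nearly independent.

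The authors deposited a table of estimated counts for 54393 gene identifiers, with 1 column per library and 0 columns of other samples. Salmon and GRCm38 are named in the submitters' processing notes, with no role and no version of the tool. The values are whole numbers, so they were treated like expected counts already rounded, and no further rounding changed them. The annotation the authors used is not given in the sources used here. All 54393 versioned identifiers matched GENCODE M21, which supplied gene symbols, positions and gene types. For a symbol carried by more than 1 identifier (105 repeats), the identifier with the most counts was used in gene lists. No row lacked a gene name. Salmon divides reads that match several transcripts between them by a model, so counts of near-identical paralogs and pseudogenes depend on that model and on the reference. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes are uncertain. Total counts ran from 31714181 to 79122250 per library. The 10 most abundant genes took between 6.66% and 8.88% of counts. Libraries of the same genotype differed far beyond sampling noise (chi-square per degree of freedom of 103.9 for the 2 cKO and 194.3 for the 2 WT libraries), so they were not copies of 1 library. This does not show that they were independent samples.

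Genes were filtered with filterByExpr (minimum count 10), which left 18917 genes holding 99.9% of counts. Counts were scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) by a robust quasi-likelihood model with terms for time point and genotype, which leaves 1 residual degree of freedom. The common biological coefficient of variation was 0.286 and the prior degrees of freedom were 4.57. Each term was tested with an F test and p-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes. Log2 ratios within a time point used log2 CPM with a prior count of 2 and no test, because genotype and time together leave no residual for an interaction. The time term serves as the block, since each time point holds 1 library of each genotype, and no other replicate numbers are shared.

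Before the data were examined, 29 gene lists were fixed from textbook knowledge: basal identity, smooth muscle contraction, adhesion and basement membrane, p63 targets, luminal keratins, hormone-sensing luminal, luminal progenitor, milk and secretory, Notch, Wnt, epithelial-mesenchymal transition, cell cycle, p53 targets, interferon response, antigen presentation, lipid synthesis, dissociation stress, mitochondrially encoded, and markers of 11 other cell types or tissues. Some genes stand in more than 1 list. Lists were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists, and again with an estimated correlation and with fry. Members were also counted over all genes and adjusted over the list alone. The genes to be named were fixed at the same time. They were Trp63, Trp53 and Trp73. To these were added genes with an adjusted p under 0.05 for genotype, the same sign at both time points and at least 5 CPM in the higher genotype, the 12 highest and 12 lowest in log2 fold change at most. From each list came up to 4 passing members with the smallest p or, where fewer than 2 passed, the 2 with the highest mean CPM. The rule also took the 8 highest and 8 lowest genes for time under the same criteria, and the 8 genes of at least 10 CPM whose log2 ratios differed most between time points. Genes with names beginning Gm or ending in Rik and pseudogenes were counted, not named. Members named only because they passed adjusted over the list alone were picked after their values were seen.

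The fit was tested on simulated counts drawn from the real means and library sizes for the 18917 genes, for the genotype effect with the time term. It recovered 13 of 50 genes changed 2-fold, 44 of 50 changed 4-fold, and 50 of 50 changed 8-fold and 16-fold. It called 5 of 18717 unchanged genes. Changed genes came from those with a mean of at least 5 CPM. Each simulated gene had the spread of the fitted trend at its level, and a genotype effect that was the same at both time points. Real genes with a wider spread would be recovered less often. A second simulated draw held 1 list (cell cycle) shifted 2-fold, with genes drawn independently of each other. Camera called that list with the preset correlation (adjusted p = 3.21e-24) and not with an estimated correlation (adjusted p = 0.946). It called 0 of 28 other lists, which says nothing on false calls where genes of a list vary together.

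Alternatives fixed beforehand were DESeq2's size factors and upper-quartile factors in edgeR, no count filter, at least 10 counts in every library, DESeq2 1.42.0, limma-voom, no covariate, and leaving out each library with no covariate, where the lone library of an arm was assumed to vary like the other arm. Ratios within a time point were recomputed with DESeq2's size factors, a prior count of 0.5 and a minimum of 1 CPM. Switching off the robust option was added after seeing the data. List medians within a time point were also ranked among 10000 random lists of the same size matched on mean level. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.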

Results

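Transcriptomes of mouse mammary cells were compared between wild-type (WT) glands and glands with a conditional knockout (cKO) of ΔNp63. This is the N-terminally truncated form of the transcription factor p63 that basal epithelial cells express. Recombination was driven from an inducible keratin 14 Cre line by tamoxifen given at puberty, at 4 weeks of age. Glands were taken either 10 days or 5 weeks later. Dissociated cells carrying CD45, CD31 or Ter119 (markers of leukocytes, endothelium and red cells) were sorted out, and 100000 of the remaining cells were used per library. These were not epithelial cells alone. Fibroblast markers summed to between 39010 and 74575 CPM per library, and luminal keratin and differentiation genes to between 8174 and 10696 CPM. A genotype difference can therefore also reflect the mix of cells. There were 4 libraries, 1 for each genotype at each time point, so each genotype had n = 2. The deposited gene counts summed to 33363255 for WT and 31714181 for cKO at 10 days, and to 79122250 for WT and 34230566 for cKO at 5 weeks. Between 27232 and 29617 genes had at least 1 count per library. Spearman correlations of log2 CPM (counts scaled to library size) across the 18917 tested genes, which are not independent replicates, lay between 0.959 and 0.975 for the 6 pairs of libraries, and the highest was between the 2 cKO libraries. The labels also give gland ages of 5 and 35 weeks, and the older of these cannot be reached from tamoxifen at 4 weeks plus 5 weeks, so age was not used.

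The deleted gene was examined first. Trp63 (ENSMUSG00000022510.14, GRCm38 chromosome 16, 25683763 to 25892102) stood at 46.8 CPM in WT and 12.8 CPM in cKO at 10 days, and at 160.5 CPM in WT and 25.5 CPM in cKO at 5 weeks. Its transcripts were lower in cKO at both time points, in the direction the genotype labels give. In WT they were higher at 5 weeks than at 10 days, as those of the basal keratin gene Krt5 were (7826 against 1018 CPM). Fewer basal cells in cKO, or squamous tissue carried over into WT, would give the same direction. The Trp63 difference therefore does not by itself show recombination. The log2 fold change was -2.26 (SE 0.267, n = 2 per genotype), or 4.80-fold lower. The unadjusted p of edgeR's quasi-likelihood test was 0.000237, and the adjusted value over all genes was 0.107, which missed the 0.05 threshold. The log2 ratio was -1.86 at 10 days and -2.65 at 5 weeks. In fits that left out a library and also lacked the time term, the log2 fold change was -1.29 without WT at 5 weeks and -3.07 without WT at 10 days. Gene-level counts hold all isoforms, including the full-length ones and any transcripts of the recombined allele. Its relatives Trp53 (65.6 and 56.8 CPM in cKO against 108.7 and 103.0 in WT at 10 days and 5 weeks; log2 fold change -0.79, adjusted p = 0.271) and Trp73 (0.72 and 0.88 CPM against 1.68 and 7.76; log2 fold change -2.22, adjusted p = 0.319) did not pass the threshold either.

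The genotype comparison asked which genes differ between cKO and WT libraries with time point held constant. The genes called were nearly all lower in cKO, and several are known from stratified epithelia. Krt13, a keratin of non-cornified squamous epithelia, stood at 54.0 CPM in WT against 0.66 in cKO at 10 days, and at 357.6 against 5.15 at 5 weeks (log2 fold change -6.21, SE 0.252, adjusted p = 0.00998). Krt6b, an inducible keratin, was lower with a log2 fold change of -5.39 (SE 0.239), and Krt15, a keratin of basal layers, with -4.03 (SE 0.294). The desmosomal cadherin Dsg3 (-4.79, SE 0.227), the connexin gene Gjb2 (-3.83, SE 0.266), the protease inhibitor gene Spink5 (-5.95, SE 0.376) and the keratinocyte differentiation gene Krtdap (-4.68, SE 0.281) were also lower. The others were the cornified envelope gene Sprr2a2 (-6.19, SE 0.415), the homeobox gene Pitx1 (-6.06, SE 0.443) and the transmembrane protease gene Tmprss11g (-4.79, SE 0.303). Across the alternatives the estimates of most of them ranged wider than these SEs, with Spink5 from -9.72 to -2.98 and Krt15 from -5.51 to -2.46. Sprr2a2 and Krt6b have close paralogs, with which reads can be shared, so their individual values are uncertain. Pitx1, Spink5 and Tmprss11g held only 6, 3 and 9 counts in cKO at 10 days, so the sizes of their changes are uncertain too. Mum1l1, which encodes a protein with a PWWP domain, was higher in cKO, at 85.7 and 67.1 CPM against 9.52 and 8.33 in WT (log2 fold change 3.09, SE 0.220, adjusted p = 0.034).

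Altogether 11 of 18917 genes passed an adjusted p of 0.05 in edgeR, 10 lower and 1 higher in cKO. An unadjusted p under 0.05 was reached by 2196 genes, of which 1098 were lower and 1098 higher, where 946 were expected by chance. The number of calls differed between fits. DESeq2 called 512 genes (276 lower and 236 higher) and limma-voom 29 (25 lower and 4 higher), each with the 11 among them. With DESeq2's size factors edgeR called 5 of the 11 and with upper-quartile factors 3, all lower, and Mum1l1 was not among them (adjusted p = 0.0512 and 0.0563). By contrast, edgeR without the time term called 0, with 2182 genes at an unadjusted p under 0.05. Leaving out a library, with no time term, gave 60 calls without WT at 10 days (3 of the 11 among them), 1 without WT at 5 weeks (none of the 11), 0 without cKO at 10 days (1396 at an unadjusted p under 0.05) and 0 without cKO at 5 weeks (1111).

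**Figure D1:**
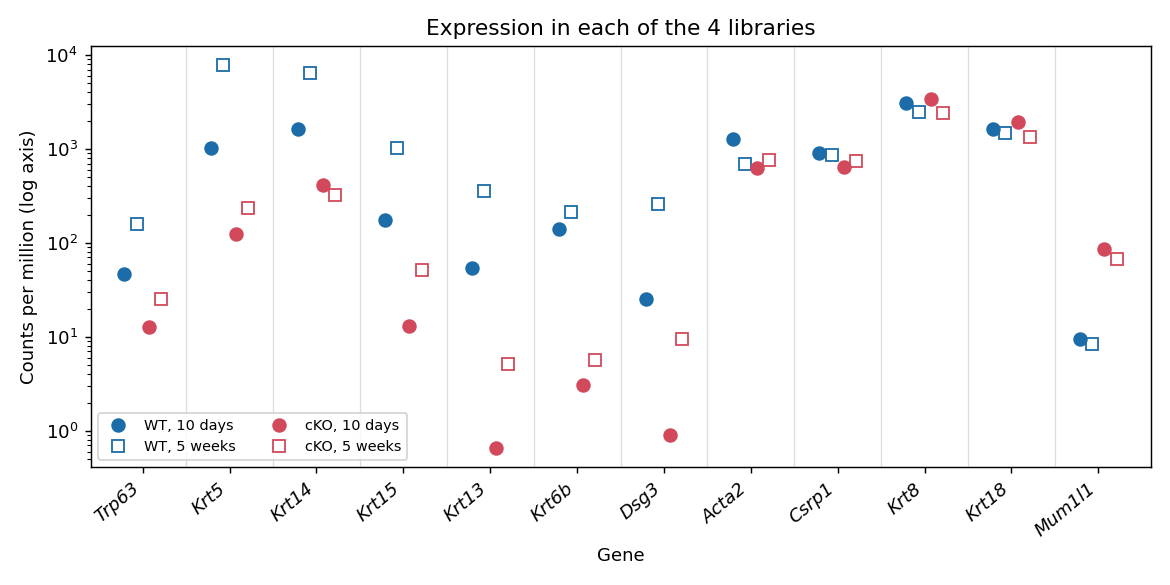
CPM (log axis) of 12 genes in each of the 4 libraries; filled circles are 10 days, open squares 5 weeks, blue WT and red cKO, and each point is 1 library. Trp63, Krt5, Krt14, Krt15, Krt13, Krt6b and Dsg3 lay lower in cKO at both time points, Krt8 and Krt18 lay close together, and Mum1l1 was at 9.52 and 8.33 in WT against 85.7 and 67.1 in cKO.

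Basal epithelial genes were lower in cKO as a group. Of the 27 basal identity genes, 1 (Krt15) passed the threshold over all genes. Adjusted over the list alone, 10 were lower and 2 (Cav1 and Procr) higher. The major basal keratins Krt5 and Krt14 were among those lower. Krt5 stood at 1018 CPM in WT against 123.0 in cKO at 10 days and at 7826 against 235.8 at 5 weeks (log2 fold change -4.05, SE 0.657, adjusted p = 0.215 over all genes and 0.00884 over the list alone). Krt14, whose promoter drives the Cre, stood at 1637 against 411.5 and at 6510 against 321.0 CPM (log2 fold change -3.17, SE 0.728, adjusted p = 0.287 over all genes and 0.026 over the list alone). Sparc, another listed gene, was at 3097 and 1793 CPM in WT and at 1526 and 3947 CPM in cKO. Among 32 genes published as p63 targets in epithelia, 18 were lower and 0 higher adjusted over the list alone and 0 over all genes. The median log2 fold change was -0.94. They included the cadherin gene Cdh3 (-2.14), the Notch ligand gene Jag2 (-1.78) and the desmosomal gene Perp (-2.12), picked after their values were seen. Of 25 adhesion and basement membrane genes, 5 were lower adjusted over the list alone and 0 over all genes: the laminin chain genes Lamb3 (-1.37) and Lama3 (-1.13), the collagen genes Col17a1 (-2.33) and Col7a1 (-1.63), and the integrin adaptor gene Fermt1 (-0.96). Col4a1 and Col4a2, the most abundant of that list, had log2 fold changes of 0.10 and 0.01. Of 16 epidermal differentiation genes, Krt6b and Krtdap passed over all genes and 8 were lower adjusted over the list alone, with a median of -3.27. Without a library, and with no time term, that median ran from -5.18 without cKO at 5 weeks to -1.54 without WT at 5 weeks. These 4 lists were lower than other genes by camera with a preset correlation of 0.01 (adjusted p = 0.000768 for basal identity, 7.64e-10 for p63 targets, 0.003 for adhesion and 8.54e-11 for epidermal differentiation). Each of them had adjusted p = 0.594 with an estimated correlation.

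The contractile genes that myoepithelial cells share with smooth muscle were not called. None of the 20 tested passed, either over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05. Their median log2 fold change was -0.18, with quartiles of -0.42 and 0.09 (camera adjusted p = 0.557). The median log2 ratio was -0.34 at 10 days (quartiles -0.57 and 0.06) and 0.12 at 5 weeks (quartiles -0.08 and 0.45). Acta2, smooth muscle actin, was at 1267 and 690.3 CPM in WT against 624.0 and 771.5 in cKO at 10 days and 5 weeks (log2 fold change -0.43, SE 0.388), and Csrp1 was at 912.5 and 856.8 against 644.3 and 743.1. Markers of pericytes and vascular smooth muscle, cells that express the same contractile genes and that the sort does not remove, had a median log2 fold change of 0.59 (camera adjusted p = 0.00195, and adjusted p = 0.594 with an estimated correlation).

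Few genes of the luminal lineage passed. Krt8 and Krt18, the keratins of luminal cells, had log2 fold changes of 0.06 (SE 0.369) and 0.07 (SE 0.336). The 18 luminal keratin and differentiation genes as a list did not pass (median -0.16, camera adjusted p = 0.105), although adjusted over the list alone Ehf (-1.54) and Ovol1 (-1.88), both epithelial transcription factors, were lower and Prom1 (0.86) was higher. Hormone-sensing luminal genes were higher as a list (22 genes, median 0.48, camera adjusted p = 0.004, and adjusted p = 0.712 with an estimated correlation). None passed singly, and the median was 0.91 at 10 days and 0.08 at 5 weeks. Without WT at 10 days this list's median was 0.13 (adjusted p = 0.613), and without cKO at 10 days 0.38 (adjusted p = 0.0632). Prlr, the prolactin receptor gene, was at 444.8 and 586.4 CPM in WT against 836.7 and 965.6 in cKO (log2 fold change 0.82, adjusted p = 0.387), and Ptn at 377.3 and 675.4 against 692.7 and 714.6. Luminal progenitor genes (median -0.17, camera adjusted p = 0.940; Mfge8 -0.31, Plet1 -0.29) and milk and secretory genes (median -0.12 with a mean of 0.12, camera adjusted p = 0.647; Mfge8 and Xdh, which had a log2 fold change of 1.14) did not pass as lists. Adjusted over the list alone, 0 of 21 and 1 of 19 passed, the latter being Glycam1 (2.16). Notch pathway genes (21 tested, median 0.05, mean -0.04, camera adjusted p = 0.940; Notch3 0.05, Notch1 -0.41) and Wnt response genes (22 tested, median -0.06, camera adjusted p = 0.375; Myc 0.40, Lrp5 -0.08) each had 1 member lower adjusted over the list alone, the ligand gene Jag2 and the Wnt inhibitor gene Notum (-4.53). Among epithelial-mesenchymal transition genes 1 of 20 was higher adjusted over the list alone, Zeb2 (1.07), and the list did not pass (median 0.26, camera adjusted p = 0.0702; Fn1 0.36, Vim 0.59). Of 24 p53 target genes 0 passed adjusted over the list alone (median 0.09, camera adjusted p = 0.785; Btg2 0.14, Trp53inp1 0.94).

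Cell cycle genes of S and G2/M phase were lower in cKO. Of 35 tested, 26 were lower and 0 higher adjusted over the list alone, 0 passed over all genes, and 31 were lower at both time points. The median log2 fold change was -1.52 (camera adjusted p = 1.62e-16, and adjusted p = 0.594 with an estimated correlation), and without a library, with no time term, it ran from -2.24 to -0.91. Mki67, the proliferation marker, stood at 43.6 CPM in WT against 6.33 in cKO at 10 days and at 87.2 against 29.1 at 5 weeks (log2 fold change -2.17, adjusted p = 0.0128 over the list alone). Top2a, the replication-linked topoisomerase gene, stood at 33.9 against 4.85 and at 60.7 against 25.1. Both were picked after their values were seen. The most abundant members, Pcna (log2 fold change -0.20) and Mcm4 (-0.05), did not pass. Genes of fatty acid and cholesterol synthesis were lower as a list (25 genes, median -0.41, camera adjusted p = 0.00165, and adjusted p = 0.732 with an estimated correlation), with 0 passing adjusted over the list alone. Their median log2 ratio was 0.02 at 10 days and -1.16 at 5 weeks, and without WT at 5 weeks the list's median was -0.07 (adjusted p = 0.469). Fasn, the fatty acid synthase gene, was at 453.1 and 350.0 CPM in WT against 364.0 and 239.6 in cKO, and Scd1 at 198.5 and 391.2 against 275.3 and 404.6.

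Interferon-stimulated genes were higher in cKO. All 26 tested lay above WT at both time points, 16 were higher adjusted over the list alone and 0 over all genes. The median log2 fold change was 0.91 (camera adjusted p = 1.56e-12, and adjusted p = 0.594 with an estimated correlation). Ifit1, an inhibitor of viral RNA translation, stood at 6.13 CPM in WT against 33.1 in cKO at 10 days and at 7.25 against 23.4 at 5 weeks (log2 fold change 2.06, adjusted p = 0.0144 over the list alone, picked after its values were seen). The guanylate-binding protein gene Gbp2 was at 45.5 against 133.3 and at 58.2 against 103.9 CPM (log2 fold change 1.19, adjusted p = 0.0144 over the list alone), and Stat2 had a log2 fold change of 0.50. Markers of leukocytes, cells that also express these genes, moved in the same direction: lymphocyte markers had a median of 1.37 (0.86 to 1.60 without a library) and myeloid markers of 0.85 (0.46 to 1.33). Antigen presentation genes (18 tested, 0 passing singly, median 0.39) were higher as a list (camera adjusted p = 0.00261, and adjusted p = 0.594 with an estimated correlation). The list was not called without WT at 5 weeks (median 0.28). Its median was 0.23 without cKO at 10 days and 0.71 without WT at 10 days. H2-K1 and H2-D1, the most abundant, had log2 fold changes of 0.08 and 0.20. Immediate early and heat shock genes that respond to tissue dissociation were also higher as a list (27 tested, 0 passing singly, median 0.44, camera adjusted p = 0.00261, and adjusted p = 0.727 with an estimated correlation), but not without cKO at 10 days (median 0.26, adjusted p = 0.103). Fosb was at 7563 and 8198 CPM in WT against 12270 and 9381 in cKO, and Fos at 3607 and 4521 against 6107 and 5376.

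Markers of other cell types were measured in the same libraries. Fibroblast markers were abundant in all 4 libraries: Col3a1 stood at 13514 and 7054 CPM in WT and 7365 and 19638 in cKO at 10 days and 5 weeks, and Gsn at 4235 and 9363 against 13620 and 10361. The sort does not remove fibroblasts. As lists, markers of fibroblasts (20 genes, median 0.39, camera adjusted p = 0.003), pericytes (above), endothelium (16 genes, median 0.52, adjusted p = 4.7e-05), myeloid cells (20 genes, adjusted p = 5.52e-07), lymphocytes (19 genes, adjusted p = 7.12e-10), adipocytes (16 genes, median 1.23, adjusted p = 0.00023) and skeletal muscle (12 genes, median 0.86, adjusted p = 0.00113) were higher in cKO, each with adjusted p = 0.594 with an estimated correlation. None passed over all genes. Adjusted over the list alone, 2 pericyte, 1 endothelial, 3 myeloid and 2 adipocyte markers (Cd36 and Fabp4) were higher. Without cKO at 5 weeks the fibroblast list had a median of 0.01 (adjusted p = 0.611) and without WT at 5 weeks 0.28 (adjusted p = 0.0624). Without WT at 10 days the skeletal muscle list had 0.71 (adjusted p = 0.0778). Without cKO at 10 days its median was 0.37 and that of the adipocyte list 0.43, both still called. The endothelial median ran from 0.31 without cKO at 5 weeks to 0.76 without cKO at 10 days. At 10 days and 5 weeks the median log2 ratios were 1.63 and 0.48 for adipocyte and 1.18 and 0.10 for skeletal muscle markers. Levels of the most abundant markers were Pdgfrb 209.7 and 195.4 CPM in WT against 264.0 and 290.5 in cKO, Eng 52.5 and 91.4 against 90.5 and 109.3, Vwf 55.6 and 50.6 against 55.4 and 73.4, and Lyz2 21.3 and 8.29 against 36.2 and 30.4. Igkc was at 6.59 and 9.07 against 31.7 and 19.9. For Cd14 they were 139.5 and 128.3 against 95.5 and 137.9, for Ighm 12.5 and 17.7 against 15.7 and 34.9, for Lpl 449.2 and 420.0 against 602.5 and 1078, and for Fabp4 93.7 and 115.9 against 261.7 and 240.6. The skeletal muscle genes Mb and Actn3 stayed at or under 3.06 CPM. Mitochondrially encoded transcripts did not pass as a list (13 genes, median 0.16, camera adjusted p = 0.633; mt-Co1 -0.01, mt-Cytb 0.02). Nor did erythroid markers (6 genes, median -0.16, adjusted p = 0.299; Hba-a2 0.05, and Car2, lower adjusted over the list alone, at 7.52 and 27.9 CPM in WT against 2.90 and 9.13 in cKO). Glial markers (10 genes, median -0.31, adjusted p = 0.646; Erbb3 0.01, Mbp -0.42) and secretory genes of other glands (5 genes, median -0.93, adjusted p = 0.125; Aqp5 0.48, Amy1 1.36) did not pass as lists. In the last of these, Lpo (-3.26) was lower and Amy1 higher adjusted over the list alone.

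In all, 17 of the 29 lists passed for genotype with the preset correlation, 6 lower and 11 higher in cKO, and 0 with an estimated correlation or by fry's directional test. The preset p-values take genes of a list as nearly independent. Correlations estimated from the 1 residual degree of freedom were 0.113 for cell cycle genes, 0.463 for myeloid and 0.602 for lymphocyte markers. They were -0.05 for endothelial markers and for epidermal differentiation. Where genes of a list vary together, the preset p-values are too small. The fits without a library also lacked the time term, so a change in them cannot be put down to the library alone. With 1 residual degree of freedom the estimated-correlation test did not call the 1 list shifted 2-fold in simulated data either. Its misses therefore say little about shifts of that size, and larger shifts were not simulated. In the real data its smallest adjusted p for genotype over the 29 lists was 0.594. Epidermal differentiation, with a median of -3.27, had an unadjusted p of 0.0864 by this test. An adjusted p from it beside a list, for genotype or time, is thus no evidence against a shift of that list.

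**Figure D2:**
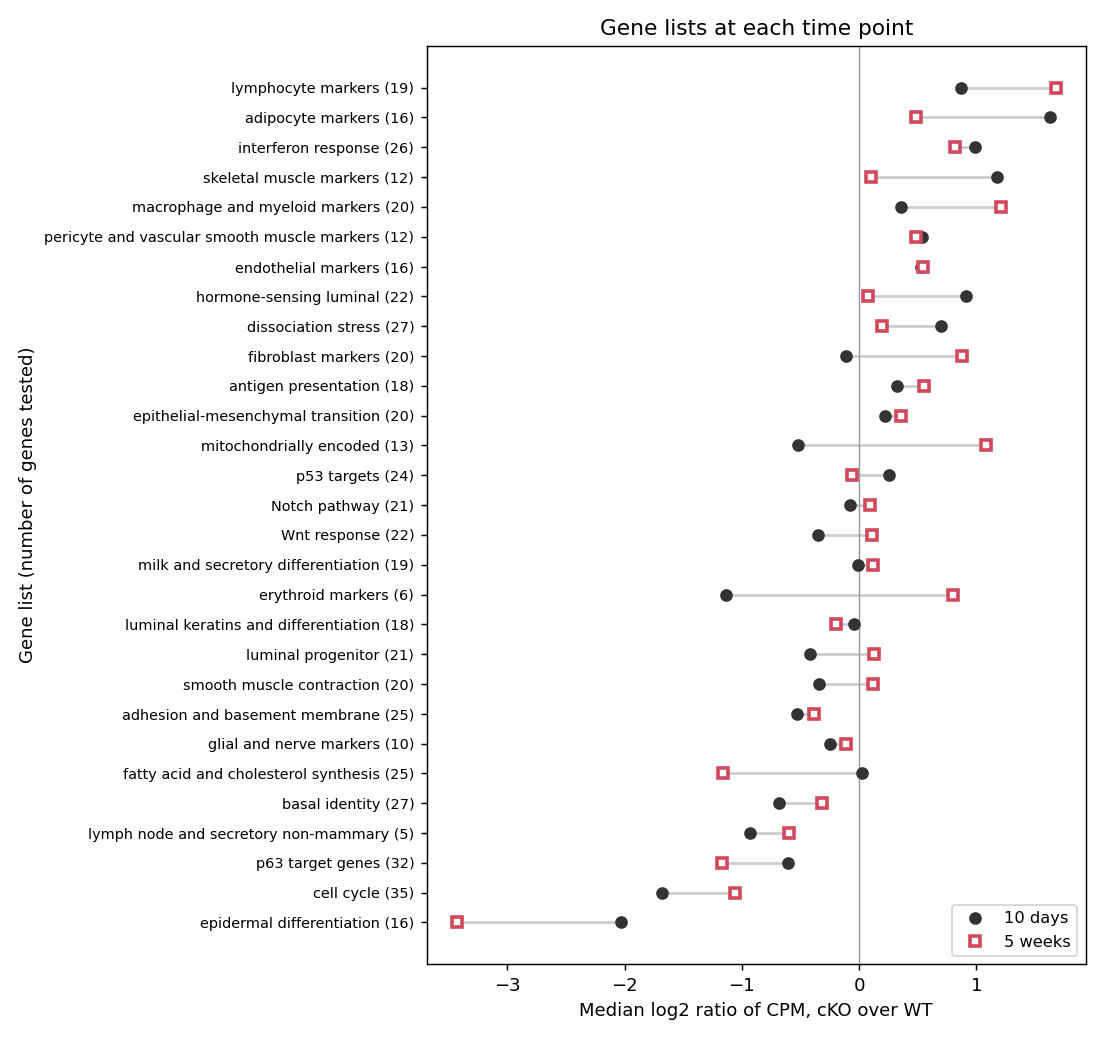
Median log2 ratio of CPM, cKO over WT, for each of the 29 gene lists at 10 days (filled circles) and 5 weeks (open squares), with the number of genes tested in brackets; each point compares 1 cKO with 1 WT library, so there is no error bar. Epidermal differentiation lay at -2.03 and -3.43, cell cycle at -1.68 and -1.06 and interferon response at 0.99 and 0.82, while mitochondrially encoded transcripts lay at -0.52 and 1.08.

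Within each time point 1 cKO library was set against 1 WT library, so these differences have no replicate check and were described without a test. Among 10987 genes with at least 10 CPM in a library, 150 were at least 4-fold lower and 90 at least 4-fold higher in cKO at 10 days, and 164 were lower and 26 higher at 5 weeks. Of these, 49 were lower and 5 higher at both times, and 2 moved in opposite directions. Across genes, which are not independent replicates, the log2 ratios of the 2 time points correlated with Pearson r = 0.376 and Spearman rho = 0.336. The genes whose ratios differed most between the time points were mostly ones high in a single library. The adipocyte genes Cfd (341.0 CPM) and Cidec (74.2 CPM) and the cytochrome P450 gene Cyp2e1 (194.5 CPM) were high in cKO at 10 days and at or under 2.12 CPM in the other 3 libraries. Entpd8 stood at 36.5 CPM in WT at 10 days and at or under 0.33 elsewhere. Muc5b, a mucin gene, was at 88.2 CPM in WT and 0.06 in cKO at 5 weeks, and at 18.3 and 1.83 at 10 days. The milk protein gene Csn1s1 was at 21.8 CPM in WT and 0.82 in cKO at 10 days and at 2.30 and 9.19 at 5 weeks. Gemin4 was at 0.12 in WT at 10 days and between 8.25 and 12.4 CPM in the others. The interferon-inducible Gvin1 was at 3.48 and 0 at 10 days and 5.80 and 27.9 at 5 weeks, WT first. Lowering the minimum to 1 CPM gave 383 lower and 231 higher genes at 10 days and 333 and 151 at 5 weeks.

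The time comparison set 5 weeks against 10 days with genotype held constant, and few genes differed. Tamoxifen was given at 4 weeks of age throughout, so this term cannot be told apart from the age of the animals. Nor can it be told apart from any batch that matched the time points. Krt13 (log2 fold change 2.82, SE 0.223, adjusted p = 0.0411), Dsg3 (3.38, SE 0.215) and the uroplakin gene Upk3a (3.18, SE 0.245) were higher at 5 weeks. Krt13 and Dsg3, which the genotype comparison also called, were higher at 5 weeks in each genotype (log2 ratios of 2.73 in WT and 2.88 in cKO for Krt13, 3.38 and 3.31 for Dsg3). Krt13 was not called with DESeq2's size factors (adjusted p = 0.063), upper-quartile factors (0.0787) or robust estimation off (0.0513), and Upk3a not with either of these factors (0.063 and 0.078). None of the 3 was called without the genotype term. With that term dropped and a library left out none was called either, and without WT at 5 weeks the estimates for Krt13 and Dsg3 turned to -2.41 and -0.46, as the genotype difference then entered them. Ceacam2, a cell adhesion gene, went from 83.7 and 55.0 CPM in WT and cKO at 10 days to 0.08 and 0.18 at 5 weeks (log2 fold change -9.25, SE 0.498). The complement protease genes C1s2 (-3.94, SE 0.267) and C1rb (-4.01, SE 0.317) were lower as well. Ceacam2, C1s2 and C1rb each have a close paralog, so their counts are uncertain. The other 6 lower genes were 4 processed pseudogenes and 2 genes with provisional symbols. In all 12 genes passed in edgeR, 3 higher and 9 lower, and 1013 had an unadjusted p under 0.05 where 946 were expected by chance. With DESeq2's size factors the split was 1 higher and 8 lower. DESeq2 called 192 genes (108 higher and 84 lower), limma-voom 39 (15 higher and 24 lower) and edgeR with no filter 638 (365 higher and 273 lower), each with the 12 among them. In edgeR 1 was called without the genotype term. With that term also dropped, 0 were called without WT at 5 weeks (626 at an unadjusted p under 0.05) or without cKO at 5 weeks (810).

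Of the 29 lists, 9 passed for time with the preset correlation, 6 higher and 3 lower at 5 weeks, and 0 with an estimated correlation (adjusted p = 0.869 for each of the 9). Cell cycle genes were higher (median 1.06, camera adjusted p = 1.62e-13), with 31 of 35 higher in both genotypes and 0 passing adjusted over the list alone. Epidermal differentiation genes were higher (median 1.90, camera adjusted p = 1.59e-10, 5 passing adjusted over the list alone). The p63 targets (median 0.26, adjusted p = 0.0298), mitochondrially encoded transcripts (0.60, adjusted p = 0.000388), endothelial markers (0.44, adjusted p = 0.000852) and erythroid markers (1.42, adjusted p = 0.000388) were higher. Interferon response genes (-0.35, adjusted p = 2.29e-06), myeloid markers (-0.34, adjusted p = 0.0345) and adipocyte markers (-0.71, adjusted p = 0.0298) were lower. The p63 targets (0.31, adjusted p = 0.151) and myeloid markers (-0.27, adjusted p = 0.0831) were not called without the genotype term, nor were adipocyte markers with at least 10 counts in every library (-0.24, adjusted p = 0.0986). Without a library, with no genotype term, 1 to 8 of the 9 lists stayed called. Medians turned over without WT at 5 weeks for epidermal differentiation (-0.49), p63 targets (-0.56) and myeloid markers (0.22), and without cKO at 10 days for interferon response (0.13) and adipocyte markers (0.55). Within each genotype 1 library was set against 1, with no test. Medians in WT and cKO were 0.65 and 1.26 for cell cycle, 2.06 and 1.43 for epidermal differentiation, 0.40 and 0.50 for endothelial, 0.72 and 1.89 for erythroid and -0.24 and -0.46 for interferon response genes. They were 0.62 and -0.03 for p63 targets, -0.02 and 1.40 for mitochondrially encoded transcripts, -0.53 and 0.10 for myeloid and 0.04 and -1.18 for adipocyte markers. The remaining 20 lists did not pass for time.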

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

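The tests on the keratin and interferon patterns below were chosen after the results were seen. The results listed first moved in opposite directions at the 2 time points by at least 0.5 in log2 both ways; with 1 cKO and 1 WT library per time point, none of these differences was tested.

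Among the named genes, 5 that encode extracellular matrix proteins were lower in cKO at 10 days and higher at 5 weeks: the log2 ratio of Col3a1 was -0.88 and 1.48, a difference of 2.35, and that of Sparc was -1.02 and 1.14, a difference of 2.16. Fn1 differed by 1.99 (-0.64 and 1.35), Col4a2 by 1.41 (-0.70 and 0.72) and Col4a1 by 1.22 (-0.51 and 0.70). The adhesion and basement membrane list, which holds Col4a1 and Col4a2, did not follow them (medians -0.53 and -0.38), and fibroblast markers had medians of -0.11 and 0.88. The mitochondrially encoded list had medians of -0.52 and 1.08, a difference of 1.60, with mt-Co1 differing by 1.03 and mt-Cytb by 1.05. Erythroid markers had medians of -1.14 and 0.80, a difference of 1.94, and Hba-a2 differed by 2.13. Csn1s1 differed by 6.63 (-4.66 and 1.98), Ceacam2 by 1.45 (-0.61 and 0.85, at or under 0.18 CPM at 5 weeks), and Gvin1 by 8.54 (-6.29 and 2.26), where cKO at 10 days held 0 counts, so that its first ratio depends on the prior count.

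Basal and squamous keratin genes were lower in the cKO libraries while contractile genes were not called. Squamous tissue carried over into WT at 5 weeks alone would leave the 10 day libraries untouched, so it does not account for the difference there. The 10 day difference was known when this explanation was written down, so it is no separate test. The epidermal list had a median of -2.03 at 10 days (bootstrap 95% interval over genes -4.80 to -0.96, 1 library per genotype, so with no spread between libraries). That interval missed a bound of -1 set first; the bound was moved to 0, the value the explanation gives, after this was seen. An even loss of basal cells that also supply the contractile transcripts would lower these and Krt14 alike. The contractile list did not fall with Krt14: its median was -0.18 (quartiles -0.42 and 0.09) against -3.17 for Krt14. At 10 days the contractile median was -0.34 (quartiles -0.57 and 0.06) against -1.99 for Krt14, and at 5 weeks 0.12 against -4.34. Acta2 itself was at -1.02 at 10 days, so a partial loss there stays open. Contractile transcripts from pericytes and vascular smooth muscle, whose markers were higher in cKO, would hide a loss. The contractile list therefore cannot decide whether basal cells were lost. Carry-over into WT at 5 weeks as the cause of a larger difference at 5 weeks cannot be told apart from a loss of ΔNp63-dependent expression: the epidermal median at 5 weeks minus that at 10 days was -1.40 (interval -2.39 to 1.59), which includes 0. Carry-over of one kind of squamous tissue into both WT libraries cannot be told apart from such a loss either. The interquartile range of the log2 ratio between the 2 WT libraries over 9 epidermal genes was 1.64, where a single source would scale its genes alike, and the sort does not remove keratinocytes. A genotype effect on basal cells remains a hypothesis.

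Interferon response genes were higher in both cKO libraries, as were leukocyte markers, although cells carrying CD45 were sorted out. At 10 days the interferon median exceeded the myeloid median by 0.63 (bootstrap 95% interval over genes 0.13 to 1.02). With 1 library per genotype, the intervals given here hold no spread between libraries. They also ignore that genes of a list can vary together. The 10 day value therefore cannot decide whether more myeloid cells at an unchanged level per cell were the whole cause. At 5 weeks the order was the opposite. The interferon median lay 0.39 below the myeloid median (difference -0.39, interval -0.78 to -0.09). It lay 0.85 below the lymphocyte median (difference -0.85, interval -1.20 to -0.59). These intervals have the same limits and cannot decide either, so more leukocytes of either kind stay open there. At 10 days more lymphocytes cannot be told apart from a response of the sorted cells, since the interferon median lay 0.12 above the lymphocyte median (interval -0.13 to 0.83) with all lymphocyte markers together at 56.1 to 140.8 CPM per library. An interferon response linked to genotype stays open as a hypothesis.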

How the results depend on the processing

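The result without robust estimation was added after seeing the data. For genotype, edgeR called 5 genes with DESeq2's size factors and 3 with upper-quartile factors, all among the 11. Requiring at least 10 counts in every library removed Pitx1, Spink5 and Tmprss11g before testing. With that filter edgeR called 16, including the other 8 of the 11. Without robust estimation edgeR called 13 (all 11 among them). It called 1235 with no filter (670 lower, 565 higher), where the prior degrees of freedom became infinite so that the spread of single genes no longer counted; DESeq2 called 512 and limma-voom 29. Without the time term edgeR called 0 (2182 at an unadjusted p under 0.05), and without a library between 0 and 60 (1396 and 1111 at an unadjusted p under 0.05 where the count was 0). For time the counts were 638 with no filter (365 higher, 273 lower), 192 by DESeq2 (108 and 84), 39 by limma-voom, 1 without the genotype term (569 at an unadjusted p under 0.05), and 0 to 18 without a library (626 and 810 at an unadjusted p under 0.05 for the fits with 0). The cause was not tested except where stated.

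The Trp63 log2 fold change stayed negative in all 12 alternatives, from -3.07 to -1.29, the extremes being fits without a library (-3.07 to -1.29). It passed the threshold with no filter (-2.28, adjusted p = 1.78e-16) and in DESeq2 (-2.26, adjusted p = 4.17e-09), and the adjusted p ranged up to 0.824. Each of the 11 genes called for genotype kept its sign in every alternative that tested it, but each was called in only 4 to 8 of 11 or 12. Sizes moved too: Spink5 from -9.72 to -2.98, Dsg3 from -7.30 to -2.27, Krtdap from -7.11 to -2.40, Krt13 from -8.28 to -4.21, Sprr2a2 from -8.97 to -3.78, Pitx1 from -7.71 to -3.70, Tmprss11g from -6.75 to -2.78 and Krt15 from -5.51 to -2.46. Gjb2 (-4.29 to -3.32), Krt6b (-5.88 to -4.98) and Mum1l1 (2.90 to 3.24) moved less.

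Genotype lists called numbered 15 to 19 without a library and 0 with an estimated correlation or by fry. For time they numbered 5 to 10 and 0. Only 1 of the 9 stayed called without cKO at 10 days and 4 without WT at 5 weeks. Among those 4 the p63 targets were called in the opposite direction (-0.56). Of the 17 genotype lists, 11 were called in all 7 alternatives that kept the preset correlation. The fits without a library also lacked the covariate. For time, the remaining library of one time point then carried the genotype difference into the estimate, and some estimates turned over without WT at 5 weeks: Krt13 (-2.41; -2.41 to 8.10 over these fits), Dsg3 (-0.46 to 7.22), p63 targets (-0.56 to 0.75), epidermal differentiation (-0.49 to 4.86) and myeloid markers (-1.12 to 0.22, the highest being that fit). Others turned over without cKO at 10 days: interferon response (-0.81 to 0.13) and adipocyte markers (-1.07 to 0.55). Within each genotype Krt13, Dsg3 and the epidermal and interferon medians kept their sign, while those of p63 targets (0.62 in WT and -0.03 in cKO), myeloid (-0.53 and 0.10) and adipocyte markers (0.04 and -1.18) did not. The other time lists kept their sign but lost calls: cell cycle (0.20 to 2.05) without cKO at 10 days and without WT at 5 weeks, mitochondrial (0.12 to 1.09) without either cKO library, endothelial (0.09 to 0.72) without WT at 10 days and without cKO at 5 weeks, and erythroid (0.94 to 2.18) without cKO at 10 days. In these fits 14 of the 17 genotype medians and all 9 time medians moved more than 1.5 times. With a minimum of 1 CPM, 383 lower and 231 higher genes were at least 4-fold apart at 10 days and 333 and 151 at 5 weeks. Among named genes, 851 other estimates kept call and direction, or were uncalled and changed sign with a shift under 1 SE. Another 98 lost and 23 gained a call, and 24 uncalled ones changed sign with a shift of at least 1 SE. Each library held at least 31714181 counts. At these sizes simulated changes of 2-fold were recovered in 13 of 50 genes and of 4-fold in 44 of 50. Simulated genes had no spread of their own, so recovery in the real data can be lower. There Trp63 (4.80-fold lower) and Krt5 (16.6-fold lower) did not pass over all genes.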

Other observations

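Against 10000 random lists matched on mean level, the luminal progenitor list lay at percentile 0 at 10 days (median log2 ratio cKO over WT -0.42) and 92.7 at 5 weeks (0.13), the Wnt response list at 0.07 (-0.35) and 91.5 (0.11), and the hormone-sensing luminal list at 100 (0.91) and 88.6 (0.08). Smooth muscle contraction lay at 0.05 (-0.34) and 89.2 (0.12). These describe single pairs of libraries. Extreme percentiles were common at 10 days: mitochondrially encoded transcripts also lay at 0, erythroid markers at 0.12 and p53 targets at 99.6. Luminal keratins at 38.4 and milk and secretory genes at 48.1 were not extreme. Genes of a random list need not vary together as genes of a fixed list can, so such a percentile does not set a list apart. Calca, a neuropeptide gene that hormone-sensing cells express, stood at 232.7 CPM in WT and 5.04 in cKO at 10 days and at 1.25 and 0.50 at 5 weeks, and was singled out after its values were seen.

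Between time points 22 genes of at least 10 CPM differed at least 8-fold in the same direction in both genotypes, 11 lower and 11 higher at 5 weeks. Pseudogenes made up 27.3% of them (6 of 22), against 2.49% of the other genes at that level, and 2 pairs lay within 2 Mb of each other (13.8% of 10000 random draws had at least as many). Of the 22, 11 had been called in the time comparison, with 4 of the 6 pseudogenes among them, before these values were looked up, so no explanation was tested on them.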
